A study of Sorghum bicolor with 14 samples.

How the data were processed

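RNA was sequenced from the field-grown sorghum cultivar M35-1 at 5 stages, of which the first is the pistil 1 to 2 days before pollination (1-2 DBP) and the others are 0 to 2, 10, 20 and 30 days after pollination (DAP). The labels list 14 libraries, 3 for each stage except 30 DAP, which has 2. The 0-2 DAP libraries carry pistil as their source and seed as their tissue, so that material is described here only by its days. Total RNA was extracted with a modified Trizol method, per the labels' protocols. The same protocols name a TruSeq stranded total RNA kit and a NEBNext directional kit for every library and do not say which library was made with which kit. The accession numbers of the 1-2 DBP and 0-2 DAP libraries form 1 block and those of the 3 later stages another, and the labels do not say whether the blocks were prepared or sequenced apart. Nothing in the labels says whether the libraries of a stage came from separate plants.

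The deposited table gives TPM values for 31337 genes, per the file headers, with 1 column per stage and no column per library. TPM divides reads by gene length and scales each column to the same total, so each column summed to 1000000. It says how the transcripts of a sample are divided among genes, and a large gain in a few genes lowers every other gene. How the authors combined the libraries of a stage into 1 deposited TPM value is not stated. HISAT2, featureCounts 2.2.0 and DESeq2 are named in the submitters' processing notes without their roles. The genome build and annotation version are not given in the sources used here. Every gene of the table had a value above 0 in at least 1 column.

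The tests planned before the data were examined assumed 1 value per library: limma tests between consecutive stages, gene set tests and permutation tests of shares. With 1 value per stage none of them can be run. No p-value, SD or n is therefore given, and no difference between stages below has a replicate check. In their place each stage was compared with the one before it on the log2(TPM + 1) scale, among the 24404 genes with at least 1 TPM in at least 1 stage. A gene was counted as higher or lower when the values differed by at least 2-fold on that scale, which understates the change of genes with low TPM. The planned filter asked for 1 TPM in 2 libraries and was adapted to the stage columns. The code of the fold rule was tested on simulated data made from the 10 DAP column without noise, which checks the arithmetic and says nothing of errors in real libraries. Read counts per library were not recovered from the TPM values, so the depth behind single values is not known here and no counting interval is given. Relative depth between whole columns is taken up in the closing section only.

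The table pairs its gene IDs with no names, and 0 of the IDs occur in the reference gene table used here. Of 25 gene lists planned by pattern on gene descriptions, only the 3 that also had IDs written down beforehand could be used. They hold 3 IDs listed as kafirins (the prolamin storage proteins of sorghum endosperm), 7 listed as starch synthesis and 1 listed as flavonoid and tannin synthesis. These assignments rest on general knowledge of the sorghum genome and were not checked against an annotation. In the absence of names, the rule fixed beforehand names for each comparison the 2 IDs with the largest positive and the 2 with the largest negative difference. Only genes of at least 20 TPM in the higher stage entered. That rule also asked for a passed test and for no overlap between libraries, which could not be applied. For a list it named the 3 passing members with the highest mean TPM over the 2 stages, or 1 member if none passed. That limit was not kept, and the listed IDs printed in each comparison follow no fixed rule. Any other ID is said to have been chosen after its values were seen.

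For lists of 3 or more IDs, the median log2 difference was placed among the medians of 10000 random lists of the same size, drawn from the 201 genes nearest in mean expression to each member. Mean expression was taken over all 5 stages. Genes matched to an ID that is nearly absent at some stages and abundant at others need not share its level at either stage compared. An extreme percentile therefore adds little for such IDs, the kafirin IDs among them. Such a percentile describes these columns and is not a test of the stages. The alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, division by median-ratio size factors, quantile normalization, and, chosen after seeing the data, leaving out the 100 most abundant genes. Median-ratio factors were 1.88 for 1-2 DBP, 1.89 for 0-2 DAP, 1.03 for 10 DAP, 0.673 for 20 DAP and 0.411 for 30 DAP. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.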

Results

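Gene expression was followed from the unpollinated pistil to the seed at 30 DAP, to describe which genes are used at each step from pollination towards seed maturity. The 14 libraries fall into 5 stages, with 3 libraries at 1-2 DBP, 0-2 DAP, 10 DAP and 20 DAP and 2 at 30 DAP, and the authors' table holds 1 TPM value per gene and stage. Values below are those single values, without replicate error. A total of 14004 of the 31337 genes had at least 1 TPM in all 5 stages. The number of genes at or above 1 TPM was 21171 at 1-2 DBP, 21798 at 0-2 DAP, 20746 at 10 DAP, 19166 at 20 DAP and 15868 at 30 DAP. These numbers were not recomputed after rescaling, and 1 TPM is a stricter cutoff in columns where abundant genes take a larger share. Across 24404 genes, which are not independent replicates, Spearman's rho between consecutive stages was 0.924 for 1-2 DBP and 0-2 DAP, 0.714 for 0-2 DAP and 10 DAP, 0.890 for 10 DAP and 20 DAP, and 0.753 for 20 DAP and 30 DAP.

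The most abundant transcripts changed from stage to stage, and the IDs in this paragraph were chosen after their values were seen. Sobic.001G141300 had the highest TPM of all genes in the unpollinated pistil, at 8455, and again at 30 DAP, at 49903, with values between 1916 and 6279 in the other stages. Sobic.003G172920 led at 0-2 DAP with 13292 TPM and had 51.5 TPM at 10 DAP. Sobic.005G184700 led at 10 DAP with 41745 TPM and at 20 DAP with 67799 TPM. The 10 most abundant genes together took 4.64% of all TPM at 1-2 DBP and 6.21% at 0-2 DAP. Their share was 21.9% at 10 DAP, 31.1% at 20 DAP and 21.1% at 30 DAP, and 7 of the 10 at 10 DAP and 4 of the 10 at 20 DAP had IDs beginning with Sobic.005G.

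**Figure D1:**
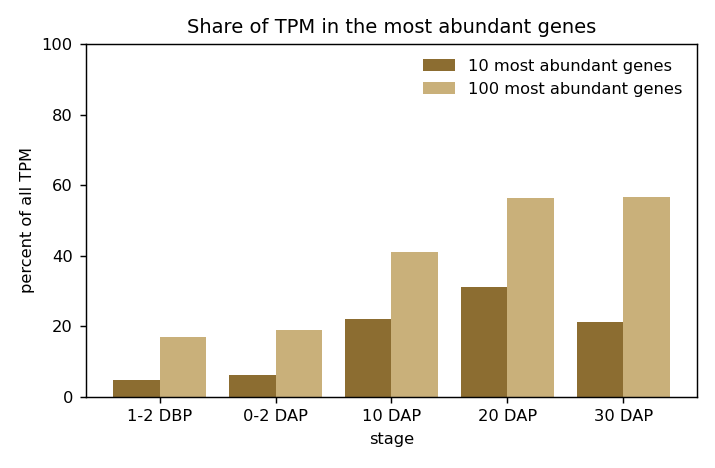
Percent of all TPM (vertical axis) taken by the 10 and by the 100 most abundant genes of each stage (horizontal axis), from 1 TPM value per gene and stage. The 100 most abundant genes took 16.9% at 1-2 DBP, 18.9% at 0-2 DAP, 41.1% at 10 DAP, 56.4% at 20 DAP and 56.6% at 30 DAP.

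The comparison of 0-2 DAP with 1-2 DBP asked which genes differ around pollination. The ID with the largest positive difference was Sobic.004G180301, at 5.42 TPM before and 2667 TPM after pollination, a log2 difference of 8.70. Sobic.001G266300 followed, with 2.01 and 609 TPM. The largest negative differences belonged to Sobic.010G130900, at 198 TPM before and 1.34 TPM after pollination, and to Sobic.003G178500, at 173 and 2.41 TPM. The 3 IDs listed as kafirins were at 0.140 TPM or below in both stages. Of the 7 IDs listed as starch synthesis, 1 was at least 2-fold higher at 0-2 DAP, Sobic.004G163700, with 17.7 TPM before and 69.4 TPM after pollination. The other 6 lay within 2-fold. Among them Sobic.010G022600, with 1.04 and 0.452 TPM, and Sobic.003G230500, with 24.7 and 22.2 TPM, were lower after pollination and the rest higher. The median of the 7 was 0.53 on the log2 scale, at the 99.01th percentile of random lists matched for expression. The single ID listed as flavonoid and tannin synthesis, Sobic.004G280800, had 8.40 TPM before and 11.7 TPM after pollination, and it stayed within 2-fold between all consecutive stages.

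Over all genes, 2152 were at least 2-fold higher at 0-2 DAP and 1587 at least 2-fold lower, while 20665 lay within 2-fold. The median log2 difference over all genes was 0.02. With pseudocounts of 0.1 and 5 the number of higher genes was 3372 and 1013.

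The comparison of 10 DAP with 0-2 DAP asked which genes differ as the seed begins to grow. The libraries up to 0-2 DAP and those from 10 DAP on carry accession numbers from 2 separate blocks that part exactly here, so any technical difference between the blocks cannot be told apart from the stage. The 3 IDs listed as kafirins, storage proteins of the endosperm, were each below 1 TPM at 0-2 DAP and at 15003 TPM or more at 10 DAP. Sobic.009G001600 had 0.140 TPM at 0-2 DAP and 39549 TPM at 10 DAP, Sobic.002G211700 had 0.0954 and 33697 TPM, and Sobic.005G185600 had 0.0690 and 15003 TPM. Together they held 8.82% of all TPM at 10 DAP, and their median log2 difference of 14.91 lay at the 99.99th percentile of matched random lists. With values this low at 0-2 DAP its size is set by the pseudocount, and it was 17.33 with 0.1, 12.69 with 5 and 13.96 after quantile normalization. The ID with the largest positive difference of all genes was Sobic.005G184700, at 0.168 and 41745 TPM, followed by the listed Sobic.009G001600. That order depends on the pseudocount. With 0.1, Sobic.002G211700, at 17.40, and Sobic.009G001600, at 17.33, stood above Sobic.005G184700, at 17.25.

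Of the 7 IDs listed as starch synthesis, 5 were at least 2-fold higher at 10 DAP, none was 2-fold lower, and 2 stayed within 2-fold. Sobic.010G022600 had 0.452 TPM at 0-2 DAP and 1971 TPM at 10 DAP. Sobic.003G230500 had 22.2 and 418 TPM, and Sobic.007G101500 had 118 and 526 TPM. Sobic.010G273800 had 276 and 274 TPM, and Sobic.010G047700 had 107 and 165 TPM, a log2 difference of 0.62 as deposited. The latter passed 2-fold after median-ratio scaling, at 1.48, and after quantile normalization, at 1.07. The median of the 7 was 2.15 on the log2 scale, at the 99.98th percentile of matched random lists, and it was 3.01 after median-ratio scaling and 2.77 after quantile normalization. The share of the 7 in all TPM was 0.0605% at 0-2 DAP and 0.369% at 10 DAP.

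The largest negative differences belonged to Sobic.002G288700, with 7040 TPM at 0-2 DAP and 1.08 TPM at 10 DAP, and to Sobic.004G337132, with 4942 and 0.477 TPM. Both were also abundant in the unpollinated pistil, at 1878 and 879 TPM. Over all genes, 2678 were at least 2-fold higher at 10 DAP and 9697 at least 2-fold lower, and the median log2 difference over all genes was -0.72. After median-ratio scaling, which moves that median to -0.02, 4816 genes were higher and 3756 lower. The higher genes made up 21.6% of the genes past 2-fold as deposited, 56.2% after median-ratio scaling, 47.7% after quantile normalization and 37.0% without the 100 most abundant genes, so higher genes led under median-ratio scaling alone.

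**Figure D2:**
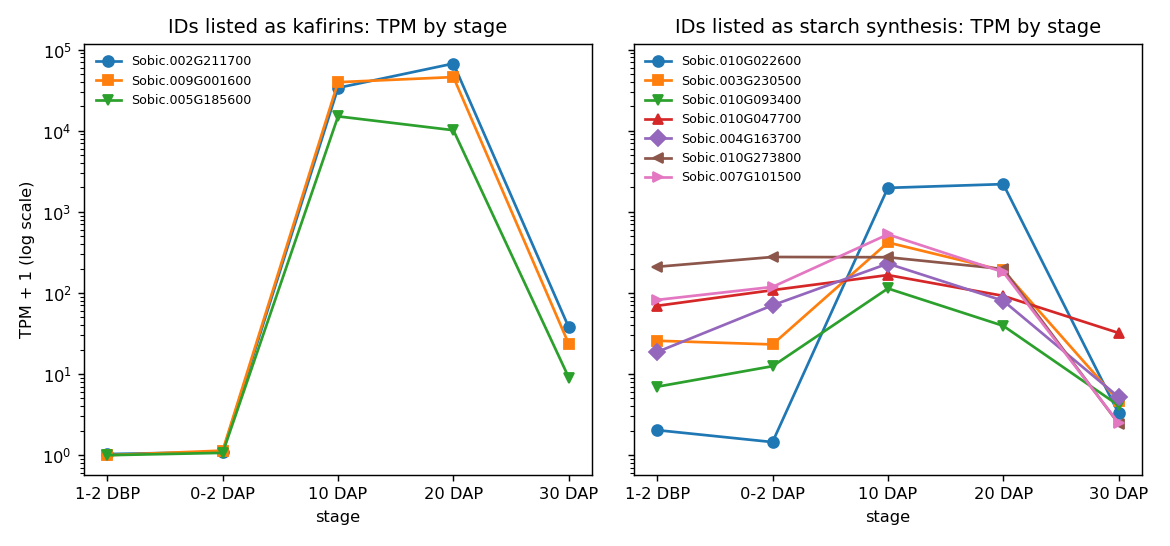
TPM + 1 on a log scale (vertical axis) at the 5 stages (horizontal axis) for the 3 IDs listed as kafirins (left) and the 7 listed as starch synthesis (right); each line is 1 ID and each point the authors' single value. The kafirin IDs stand near 1 in both early stages, at 10121 TPM or more at 10 and 20 DAP, and at 8.06 to 36.6 TPM at 30 DAP. Within each stage the starch IDs lie further apart from each other on the log scale, and they end at 1.45 to 31.1 TPM.

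The comparison of 20 DAP with 10 DAP asked which genes differ between these 2 seed stages. The 3 IDs listed as kafirins stayed within 2-fold, and their share of all TPM was 8.82% at 10 DAP and 12.3% at 20 DAP. Sobic.002G211700 had 33697 and 67112 TPM, a log2 difference of 0.99 as deposited and 1.61 after median-ratio scaling. Sobic.009G001600 had 39549 and 45724 TPM, and Sobic.005G185600 had 15003 and 10121 TPM. Their median log2 difference was 0.21 as deposited, 0.83 after median-ratio scaling and -0.38 after quantile normalization, so its sign depends on the scaling. Of the 7 starch synthesis IDs, 4 were at least 2-fold lower at 20 DAP and 3 stayed within 2-fold. Sobic.007G101500 had 526 TPM at 10 DAP and 179 TPM at 20 DAP, Sobic.004G163700 had 229 and 79.0 TPM, and Sobic.010G022600 had 1971 and 2191 TPM. The median of the 7 was -1.15 on the log2 scale against -0.47 for all genes, at the 1.56th percentile of matched random lists. After median-ratio scaling that median was -0.53, and none of the 4 IDs was past 2-fold; after quantile normalization it was -0.80, with Sobic.004G163700 and Sobic.007G101500 past 2-fold.

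Sobic.004G196900, the ID with the largest positive difference, had 0.169 TPM at 10 DAP, 852 TPM at 20 DAP and 12834 TPM at 30 DAP. Sobic.001G418500 followed with 0.193, 813 and 2126 TPM. Sobic.001G266300, which was among the largest positive differences at pollination, had 493 TPM at 10 DAP and 0.398 TPM at 20 DAP. Sobic.005G064400 had 797 TPM at 0-2 DAP, 142 TPM at 10 DAP and 0.0120 TPM at 20 DAP. Over all genes, 1033 were at least 2-fold higher at 20 DAP and 4586 at least 2-fold lower. With a pseudocount of 0.1, 1598 were higher and 6999 lower, and with 5, 554 were higher and 2155 lower. After median-ratio scaling 1955 were higher and 2144 lower, and the higher genes made up 47.7% of the genes past 2-fold against 18.4% as deposited.

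The comparison of 30 DAP with 20 DAP covers the end of the series, where the labels list 2 libraries. All 3 kafirin IDs and all 7 starch synthesis IDs were at least 2-fold lower at 30 DAP. Sobic.002G211700 had 67112 TPM at 20 DAP and 36.6 TPM at 30 DAP, Sobic.009G001600 had 45724 and 22.5 TPM, and Sobic.005G185600 had 10121 and 8.06 TPM. The share of the 3 in all TPM was 12.3% at 20 DAP and 0.00672% at 30 DAP. Among the starch synthesis IDs, Sobic.010G022600 had 2191 and 2.28 TPM, Sobic.010G273800 had 196 and 1.45 TPM, and Sobic.010G047700, the highest of the 7 at 30 DAP, had 91.0 and 31.1 TPM. The list medians were -10.80 and -5.34 on the log2 scale, and none of the 10000 matched random lists had a lower median. The kafirin median was -10.11 after median-ratio scaling and -8.44 after quantile normalization, and the starch synthesis median was -4.48 with a pseudocount of 5 and -4.53 after quantile normalization. Sobic.010G047700 was the 1 member that no longer passed 2-fold after median-ratio scaling, with a log2 difference of -0.83. Sobic.004G280800, the ID listed as flavonoid and tannin synthesis, had 9.74 TPM at 10 DAP, 7.53 TPM at 20 DAP and 5.45 TPM at 30 DAP, and the sign of its small differences between these stages flipped under both scalings.

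The largest negative differences of all genes belonged to Sobic.002G211501, at 8357 and 1.69 TPM, and to Sobic.005G186300, at 4289 and 0.861 TPM. The largest positive differences belonged to Sobic.002G075800, at 15.6 TPM at 20 DAP and 2572 TPM at 30 DAP, and to Sobic.001G028600, at 3.63 and 510 TPM. Sobic.002G075800 also had 459 TPM at 10 DAP, so its value at 20 DAP lay below both neighbours. Over all genes, 2204 were at least 2-fold higher at 30 DAP and 6890 at least 2-fold lower. With a pseudocount of 5 these counts were 1431 and 3094. After median-ratio scaling the numbers were 4569 and 4977, and the higher genes made up 47.9% of the genes past 2-fold against 24.2% as deposited. After quantile normalization the direction of the split turned, with 4146 higher and 4048 lower, or 50.6% higher.

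**Figure D3:**
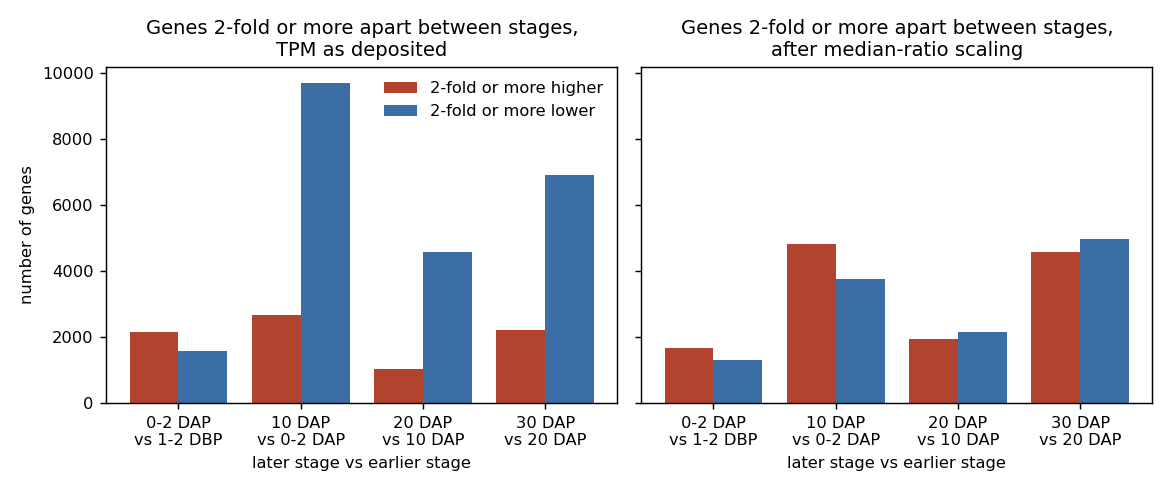
Number of genes (vertical axis) at least 2-fold higher or lower in the later than in the earlier stage for the 4 consecutive comparisons (horizontal axis), from TPM as deposited (left) and after median-ratio scaling (right), without a test. As deposited, lower genes outnumber higher genes by 9697 to 2678 at 10 DAP; after scaling the numbers are 3756 and 4816.

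Over the whole series, 5626 of the 24404 genes as deposited stayed within 2-fold between all consecutive stages and 471 differed by 2-fold at all 4 transitions. After median-ratio scaling these numbers were 9040 and 333. The most frequent course with a difference as deposited, seen in 5036 genes, was a value at least 2-fold lower at 10 DAP than at 0-2 DAP with no other 2-fold difference. After median-ratio scaling 1880 genes showed that course, and it was no longer the most frequent, since 2150 genes were 2-fold higher at 30 DAP with no other 2-fold difference. A further 646 genes were 2-fold higher at 10 DAP, within 2-fold at 20 DAP and 2-fold lower at 30 DAP as deposited, the course of the 3 kafirin IDs. After median-ratio scaling the number was 989, and Sobic.002G211700, at 1.61 for 20 DAP against 10 DAP, was not on that course. As deposited, 8729 genes had their highest value at 1-2 DBP, 8768 at 0-2 DAP, 3719 at 10 DAP, 1085 at 20 DAP and 2103 at 30 DAP. After median-ratio scaling the stage with most maxima was 30 DAP, with 7382 genes, and 4299, 5639, 4141 and 2943 genes had their highest value at 1-2 DBP, 0-2 DAP, 10 DAP and 20 DAP.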

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

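The alternative without the 100 most abundant genes was chosen after seeing the data. The 8 counts of genes past 2-fold and the 23037 genes with a 2-fold range over the series were recomputed under each alternative, and a count is listed when it moved by more than 1.5 times; the range count did not. Between 1-2 DBP and 0-2 DAP, 3372 genes were higher with a pseudocount of 0.1, and 1013 higher and 862 lower with a pseudocount of 5. Between 0-2 DAP and 10 DAP, 1673 were higher and 6170 lower with a pseudocount of 5, 4816 and 3756 after median-ratio scaling, and 4308 and 4722 after quantile normalization. Between 10 DAP and 20 DAP, 1598 were higher and 6999 lower with a pseudocount of 0.1, 554 and 2155 with 5, 1955 and 2144 after median-ratio scaling, 1917 and 2146 after quantile normalization, and 1963 and 2927 without the 100 most abundant genes. Between 20 DAP and 30 DAP, 1431 were higher and 3094 lower with a pseudocount of 5, 4569 were higher after median-ratio scaling, and 4146 higher and 4048 lower after quantile normalization. The pseudocounts act on genes with low TPM and both scalings centre the bulk of genes by construction. The filters moved no count by more than 1.5 times, and dropping the filter left the counts equal because a gene under 1 TPM in every stage cannot reach 2-fold with a pseudocount of 1. Among the named IDs and list medians, 108 of the 414 recomputed log2 differences moved by more than 1.5 times in fold and none that passed 2-fold changed sign. The 414 include 69 for each of the 2 filters, which cannot change the value of an ID and moved none. Under median-ratio scaling 32 moved and 37 did not, and under quantile normalization the numbers were equal to these. The alternative without the 100 most abundant genes was not applied to these values. No paired analysis was possible because the table holds 1 value per stage. Fits of 2 stages alone, other variance models, the estimated correlation of list members and leaving out each replicate were not run for the same reason. Depth per gene is not known here, so values near 0 at 30 DAP, where 6744 genes are listed at 0, cannot be separated from sampling.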

Other observations

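The sets of genes described here were defined after seeing the data, the tests on recurring ratios and on the depth behind the 0-2 DAP column were chosen after their results were seen, and the checks with 500 genes or with limiting genes left out were added to 2 other tests after their values were seen. A set of 195 genes had at least 20 TPM at both 10 and 20 DAP and at least 10-fold more in each than in any of the other 3 stages. They held 31.9% of all TPM at 10 DAP, 41.1% at 20 DAP and 0.0357% at 30 DAP. The 49 of them with IDs beginning with Sobic.005G held 15.1% of all TPM at 10 DAP and 19.4% at 20 DAP. The 5 neighbours in ID order from Sobic.005G184400 to Sobic.005G184800 alone held 7.63% and 12.4%, and a run of 8 neighbours from Sobic.005G192700 to Sobic.005G193180 held 1.09% and 1.49%.

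A set of 354 genes was at least 2-fold higher at 20 than at 10 DAP and again at 30 than at 20 DAP. The share of these 354 in all TPM was 0.482% at 10 DAP, 7.94% at 20 DAP and 45.0% at 30 DAP. After median-ratio scaling, which raises each later stage against the one before and so can only add genes, 745 genes met the rule. Sobic.004G196900, with 0.169, 852 and 12834 TPM, is one of the 354. A further 447 genes had values in both the unpollinated pistil and the 30 DAP seed at least 2-fold above those at 10 and 20 DAP. After median-ratio scaling 417 genes met that rule, of which 170 were among the 447, so most of this set rests on the scaling.

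Genes that dominated 1 stage, with at least 20 TPM and at least 4-fold more on the log2(TPM + 1) scale than in any other stage, numbered 694, of which 291 belonged to 30 DAP and held 41.9% of its TPM. Their side-by-side pairs in ID order were compared with 10000 shuffles within each ID prefix. At 0-2 DAP there were 16 neighbouring pairs against a mean of 0.816, at 30 DAP 13 against 2.79, at 10 DAP 6 against 0.565, at 1-2 DBP 4 against 0.382 and at 20 DAP 3 against 0.0499. All 5 of the 5 stages lay above the 99th percentile of their shuffles, although the highest shuffle equalled the observed number at 1-2 DBP and at 10 DAP, so chance order of the IDs is argued against. Whether the same reads were divided among near-identical neighbours was not tested.

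The excess of lower over higher genes after pollination was set against the share of abundant transcripts, which grew up to 20 DAP. Between 20 DAP and 30 DAP the share of the top 100 was level, at 56.4% and 56.6%, and that of the top 10 was lower. The premise was thus absent there for the top genes as a group, but the genes themselves changed. The 195 genes high at 10 and 20 DAP held 41.1% at 20 DAP and 0.0357% at 30 DAP, and the 354 rising genes held 7.94% and 45.0%. With the 100 most abundant genes of either stage left out and the rest rescaled, the median log2 difference went from -0.72 to -0.33 between 0-2 DAP and 10 DAP and from -0.42 to -0.59 between 20 DAP and 30 DAP, and with 500 left out it was -0.24 and -0.41. The genes left out therefore do not account for the whole excess in these 2 comparisons, although no replicate spread is known for these medians. Gains among genes outside the top 100 or 500 would also lower the median, and in each of these 2 comparisons rising and falling genes were left out together. Gains elsewhere and a wider decline therefore cannot be told apart in these 2 comparisons. Between 10 DAP and 20 DAP the median went from -0.47 to -0.11 with 100 genes left out and to -0.04 with 500; the first passed the bound of -0.1 set beforehand and the second did not, so abundant genes and a wider decline cannot be told apart there. A narrower set of active genes in the older seed and a change of library kit, which the labels leave unassigned, stay open, the latter above all between 0-2 DAP and 10 DAP, where the accession blocks part, and both are untested.

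The 0-2 DAP column lists 700 genes at 0, against 1902 at 1-2 DBP, and 1802 of those 1902 genes were under 1 TPM at 0-2 DAP, with a median of 0.0534 TPM. Among low genes certain ratios between columns recur, and at most 4 of the 10 commonest were small multiples of the commonest, which argues against each column being 1 set of reads normalized once and is consistent with means over separately scaled libraries. Low values were then read as sums of up to 4 reads of 3 sizes per column. The sizes were chosen to match many of the 5173 genes above 0 and under 0.5 TPM in both columns, so genes listed at 0 did not enter. With them 26.8% were matched within a relative 1e-06, against 0.0580% with shifted sizes. Because the sizes were fitted to the same genes, that contrast is built in and lends them no support. The depth implied for 0-2 DAP was 0.835 times that of 1-2 DBP. An earlier search with up to 3 reads and fewer candidate sizes gave 0.560, and a first test on the commonest ratios gave at most 1.14. Simulated libraries returned the true depth at 0-2 DAP, 0.879, at 10 DAP, 0.871, and at 20 DAP, 0.752. At 30 DAP the depth found was 0.395 against a true 0.509, so none is given for 30 DAP. For 10 DAP and 20 DAP the search implied 0.754 and 1.81 times the depth of 1-2 DBP, with 3680 and 3677 genes listed at 0. The simulated 0-2 DAP column was shallower than the 1-2 DBP column, so the search was not shown to detect a deeper one. Its bounds were set after the result was seen, and the implied depth moved with the search settings. The depth at 0-2 DAP is therefore not settled. Deeper libraries stay open, and background reads or wider low-level transcription stay open and untested.

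The 3 IDs listed as kafirins had 8.06 to 36.6 TPM at 30 DAP, after 10121 TPM or more at 20 DAP. Carry-over of reads from the 10 and 20 DAP libraries, limited so that no abundant gene exceeds its 30 DAP value, supplied at most 35.6% of their sum when all 125 genes of 1000 TPM or more at 10 or 20 DAP set the limit. It supplied 70.8% when the 100 genes also at 2 TPM or more at 30 DAP did. Both lie under the bound of 80% set beforehand, but the second limit was set by 2 genes at 2.02 and 4.23 TPM at 30 DAP. Leaving out the gene at 2.02 TPM gave 79.5%, leaving out the gene at 4.23 TPM gave 70.9%, and leaving out both gave 80.7%. Leaving out a limiting gene can only raise the share, so that rise is no sign of carry-over. Because the limit rests on these 2 genes with low TPM at 30 DAP, carry-over and transcripts remaining in the seed cannot be told apart.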
